A study of Homo sapiens with 8 samples.

How the data were processed

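Total RNA of 8 tumour samples, 4 per group, was labelled with the dye Hy5 and hybridised to a custom microarray, per the labels' protocols. The tumours grew under the flank skin of mice inoculated with HuCCT-1 cells, and the sample titles gave the group and a number from 1 to 4. The deposited scanner files hold the raw intensity of each spot, the median of its pixels, and the median and SD of its local background, with no background subtraction or normalization, per the file headers. The scanner and its software are not given in the sources used here. Each array had 3136 spots, of which 1719 carried a human miRNA probe, 1 spot each, 1248 were blank and 24 were negative controls. The series text speaks of 985 human probes, and all 1719 in the files were used. The names are those of the array's design: an asterisk marks the minor arm of a hairpin. The 8 probes that serve several miRNAs carry all their names.

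The authors' processed intensity values are on a linear scale. They were not described, and each column was set against the scanner values of its array. Each proved to be the spot median minus the mean of the blank spots, times a factor that brings the median over probes to 25 on every array, with values under 0 set to 0. They have no value for the 8 shared probes, and they were used as an alternative after log2.

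Here, the background was corrected with normexp and an offset of 50 on all spots, log2 was taken, and the 1719 human probes were quantile normalized between arrays. Quantile normalization gives probes of the same rank the same value, so the brightest probes can be tied between arrays. One human probe, miR-4454, was saturated on all 8 arrays, and no level of it is given. A probe was called detected above the mean plus 2 SD of the negative control spots of its array, without their highest and lowest 5%. The negative controls were preferred to the blank spots because all 24 of them passed the threshold of the blank spots on every array. Raw thresholds lay between 293 and 321 units, and the median of the human probes between 271 and 305, so most human probes were close to the threshold. The 492 probes detected on at least 4 of 8 arrays were tested, 291 of them detected on all 8, and 785 were detected on none.

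Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as metformin minus control over all 8 arrays with no covariate, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. SE are those of the moderated fit. Named probes followed a rule: the 10 largest rises and falls among those past the threshold with groups that did not overlap, the 2 members with the smallest p of each of 21 lists, 5 reference probes, and up to 5 probes per direction detected on all arrays of one group and none of the other. The test, the rule, the lists and the alternatives were fixed before the data were examined. The lists held miRNA families and clusters, p53-induced miRNAs, repressors of G1 cyclins, miRNAs reported as raised by metformin or in cholangiocarcinoma, a hypoxia marker (miR-210), markers of muscle, leukocytes, red cells, fibroblasts, endothelium, skin, and liver and neural tissue, and probes for RNA fragments or rich in GC. The 15 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and adjusted over these 15. Camera with an estimated correlation called 0 of them, against 4 with the preset one. fry, which tests whether members move one way and compares with no other probes, called 5. The mean of a list per array was tested with an exact two-sided permutation test over 70 arrangements.

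The alternatives were other scalings (75th percentile or median of the probes detected on all arrays, or none), no background subtraction, an offset of 16, the authors' values, stricter and no filters, a trended robust variance, array quality weights, an exact rank-sum test, the sample number as a block, other thresholds, and each array left out in turn. After the data were seen, the array pairs were added as a random block (limma duplicateCorrelation, consensus correlation 0.54), as means, and left out in turn, and blank spots were used for detection. With pairs kept whole, the smallest exact p is 0.333.

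The fits were tested on simulated data with the means and spreads of the 492 probes, with 100 probes changed and 20 runs. For the comparison of metformin with control tumours with independent arrays, 86.4% of the changes of 0.5 in log2 and 36.2% of those of 0.3 were found, and 3.39% of the calls were false. With a correlation of 0.5 within pairs, 17.9% of the calls were false without the block and 5.68% with it, which found 75.8% of the changes of 0.5. With no probe changed, paired arrays gave calls in 11 of 20 runs without the block, at most 8 calls, and in 0 runs with it. Simulated probes varied independently of each other and all had the same correlation within pairs, as the block fit assumes. Probes on the real arrays can move together, so these shares of false calls need not hold for the data. Figures were drawn with matplotlib.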

Results

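miRNA levels were measured on 1-colour microarrays in subcutaneous tumours grown in mice from HuCCT-1 cells, an established human line of cholangiocarcinoma, the cancer of the bile duct epithelium. The 8 arrays fell into 2 groups of 4, tumours of control mice and tumours of mice given metformin. Metformin is a biguanide used against type 2 diabetes that inhibits mitochondrial complex I, and it was given intraperitoneally at 2 mg per mouse per day, 5 times a week for 31 days. Of 1719 human miRNA probes, between 458 and 652 were detected per array. The mean was 560 ± 96.0 (SD, n = 4) in control tumours and 481 ± 18.5 (SD, n = 4) in metformin tumours. The difference of -78.75 probes did not exceed the spread between arrays (exact two-sided permutation test, p = 0.286). Statistics between the groups rest on the 492 probes detected on at least 4 of the 8 arrays. The number of arrays limits the precision.

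The arrays of each group came in 2 close pairs. Arrays 1 and 2, and arrays 3 and 4, of a group correlated across probes with r from 0.991 to 0.997, against 0.975 to 0.984 between arrays of different pairs in the same group and 0.961 to 0.986 between groups (across probes, which are not independent replicates). The first principal component, with 51.3% of the variance, placed metformin arrays 1 and 2 at 5.98 and 5.79, metformin arrays 3 and 4 at 0.34 and -0.38, and the controls between -3.75 and -2.17. The labels do not say whether the arrays of a pair came from different mice, so p-values over 8 arrays measure the spread between these arrays, part of which can be technical, and are too small if a pair is a single tumour. Values with the pair as a random block, a fit chosen after the data were seen, are therefore given for the named miRNAs that passed.

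**Figure D1:**
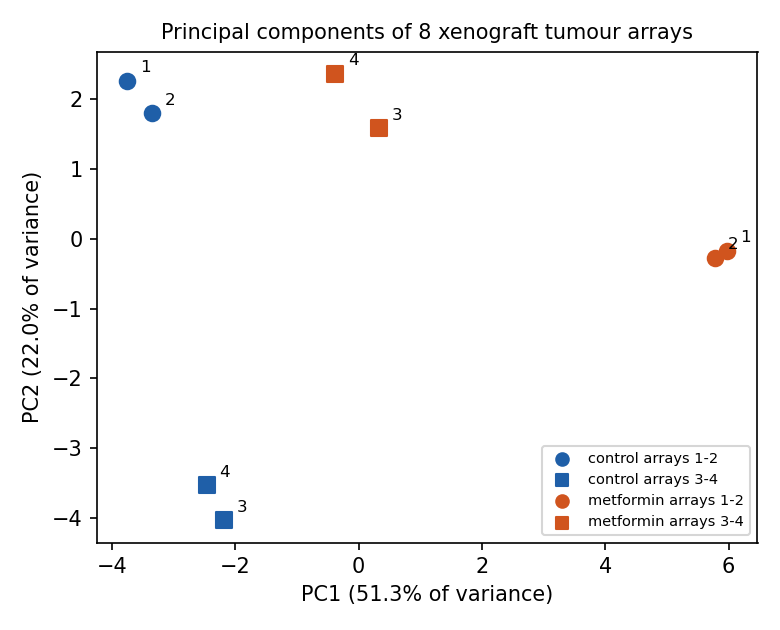
Principal components of the 8 arrays over 492 probes, with PC1 (51.3% of the variance) on the horizontal and PC2 (22.0%) on the vertical axis. Each point is an array, coloured by group, with circles for arrays 1 and 2 and squares for arrays 3 and 4. Metformin arrays 1 and 2 lie farthest from the controls, at 5.98 and 5.79 on PC1.

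The comparison of metformin with control tumours asked which miRNAs differ in abundance in tumours after treatment with the drug. The rises with the smallest p were in miR-126, the miRNA of endothelial cells, and in miR-100, which is encoded in a cluster with a let-7 gene. miR-126 rose 1.64-fold (log2 change 0.71, SE 0.08, limma adjusted p = 0.00233) and miR-100 rose 1.65-fold (0.73, SE 0.09, adjusted p = 0.00233). The falls with the smallest p were in miR-4667-5p, in miR-1275 and in miR-210, which hypoxia induces through HIF1A. miR-4667-5p was 1.48-fold lower (-0.56, SE 0.08, adjusted p = 0.00556), miR-210 was 1.58-fold lower (-0.66, SE 0.10, adjusted p = 0.00556) and miR-1275 was 1.77-fold lower (-0.82, SE 0.12, adjusted p = 0.00556). In each of these, all 4 metformin arrays lay on one side of all 4 control arrays.

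Of the 492 probes, 55 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 33 higher and 22 lower in metformin tumours, and 136 had an unadjusted p under 0.05. The changes were small on this scale, between 0.28 and 1.35 in log2 size, and 2 of the 55 reached 2-fold, both lower. Sizes depend on the processing, as an offset shrinks the log2 changes of dim probes. The median size of the 55 was 0.49 here, 0.58 with an offset of 16 and 0.41 without background subtraction. The groups did not overlap for 54 of the 55, and for 17.9% of all tested probes against 2.86% by chance if the 8 arrays are independent, which the pairs leave open. For 48 of the 55, the distance from the control mean was larger in metformin arrays 1 and 2 than in arrays 3 and 4. With the array pair as a random block 11 of the 55 passed and no other probe did, 7 higher and 4 lower. The 7 were miR-126, miR-100, miR-125b, miR-140-5p, miR-379, miR-146b-5p and the probe shared by miR-199a-3p and miR-199b-3p, and the 4 were miR-1275, miR-210, miR-4667-5p and miR-4732-5p. Of these, miR-146b-5p (log2 change 0.65, SE 0.10) stood outside the rule for named miRNAs and was named after its values were seen.

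The count depended on the scaling of the arrays: 55 probes passed after quantile normalization, 0 after scaling to the 75th percentile (40 at an unadjusted p under 0.05), 1 after scaling to the median, 1 with no scaling and 1 with the authors' values, with a median residual SD of the 55 of 0.14, 0.29, 0.27, 0.47 and 0.51, although none of them turned direction. The 55 were chosen after quantile normalization, where a small residual SD helps a probe to pass. This choice alone can make their residual SD lower in that setting. The count was also 11 without control array 2, metformin array 1 or metformin array 2, 14 without control array 4, 28 without control array 1, 6 without both metformin arrays 1 and 2, and 0 when each pair was averaged (53 at an unadjusted p under 0.05).

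Among the largest rises, the muscle miRNA miR-133a was 1.80-fold higher (log2 change 0.85, SE 0.23, adjusted p = 0.0459), with 8.92 and 8.49 in metformin arrays 1 and 2, 7.77 and 7.84 in arrays 3 and 4, and a control mean of 7.41 ± 0.10 (SD, n = 4). miR-342-3p, abundant in lymphocytes, was 1.71-fold higher (0.77, SE 0.19). It was detected on 2 of the 4 control arrays and miR-133a on 3 of the 4, so their control levels lay near the detection threshold. The probe of miR-199a-3p and miR-199b-3p, abundant in fibroblasts, was 1.68-fold higher (0.75, SE 0.14, adjusted p = 0.0149). miR-125b rose 1.66-fold (0.73, SE 0.12), miR-378c 1.62-fold (0.70, SE 0.16) and miR-140-5p 1.59-fold (0.67, SE 0.11). miR-497 and miR-195, neighbours in the genome that share a seed with miR-15 and miR-16, rose by 0.74 (SE 0.16) and 0.66 (SE 0.15), each with an adjusted p of 0.0251. Under the pair block, the adjusted p was 0.116 for miR-133a, 0.0851 for miR-342-3p, 0.109 for miR-378c and 0.0850 for both miR-497 and miR-195.

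Among the largest falls, miR-1246 was 2.54-fold lower (log2 change -1.35, SE 0.34, adjusted p = 0.0332), with 9.43 and 9.35 in metformin arrays 1 and 2, 10.68 and 10.77 in arrays 3 and 4, and a control mean of 11.40 ± 0.30 (SD, n = 4). miR-4732-5p was 2.04-fold lower (-1.03, SE 0.22, adjusted p = 0.0240), miR-4688 1.95-fold (-0.97, SE 0.26), miR-4725-3p 1.69-fold (-0.76, SE 0.17) and miR-4655-5p 1.41-fold (-0.49, SE 0.11). miR-4655-5p was detected on 1 of the 4 metformin arrays, so its level there lay near the detection threshold. miR-29c, which represses collagens, was 1.55-fold lower (-0.64, SE 0.15, adjusted p = 0.0291). Under the pair block, the adjusted p was 0.0731 for miR-1246 and miR-4725-3p, 0.0921 for miR-4688, 0.138 for miR-4655-5p, 0.0850 for miR-29c, 0.0851 for miR-3687 and 0.183 for miR-1290. miR-3687 and miR-1290 were detected on all 4 control arrays and on no metformin array, and were at least 1.34-fold and at least 1.20-fold higher in control tumours (adjusted p = 0.0240 and 0.0406). Such a bound sets the mean of the brighter group against the lowest signal called detected on each array of the other. 3 probes with the same kind of detection did not pass: miR-502-3p, detected on the metformin arrays alone (at least 1.20-fold, adjusted p = 0.0598), and miR-4646-5p and miR-2116*, detected on the control arrays alone (at least 1.17-fold and 1.08-fold, adjusted p = 0.0928 and 0.287).

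**Figure D2:**
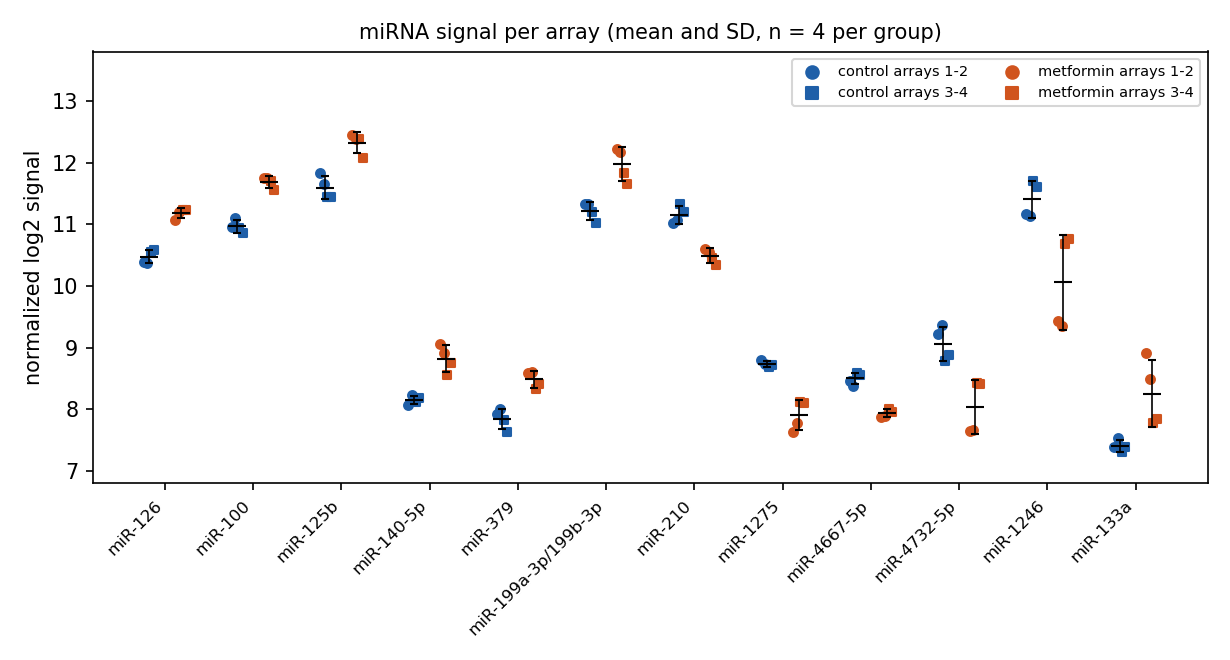
Normalized log2 signal (vertical axis) of 12 miRNA probes on each array, blue for control and orange for metformin, circles for arrays 1 and 2 and squares for arrays 3 and 4, with black bars for the mean and SD of each group (n = 4). For miR-126 the 4 metformin arrays lie between 11.06 and 11.24 and the 4 control arrays between 10.37 and 10.58, while for miR-1246 metformin arrays 1 and 2 lie at 9.43 and 9.35, below arrays 3 and 4 at 10.68 and 10.77.

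Some miRNAs of leukocytes, fibroblasts and smooth muscle, endothelium and muscle were higher in metformin tumours. Of the leukocyte list, 3 of 7 tested members rose (5 when adjusted over the list alone): miR-155 by 0.59 (SE 0.13), miR-342-3p by 0.77 and miR-142-5p by 0.55 (SE 0.12). The list mean was higher by 0.45 in log2 (limma camera adjusted p = 0.00327), and the adjusted p was 0.427 with an estimated correlation between members. Of the fibroblast and smooth muscle list, 3 of 6 rose, also 3 when adjusted over the list alone, among them miR-143 (0.57, SE 0.10), a miRNA of smooth muscle cells. Its mean was higher by 0.43 (camera adjusted p = 0.00591, and 0.427 with an estimated correlation). Both lists were above all 4 control arrays on all 4 metformin arrays (exact permutation p = 0.0286, the smallest that 70 arrangements give, adjusted p = 0.0714). With the pair block, camera was run on the t values of that fit, at the preset correlation of 0.01, and gave adjusted p of 0.000934 and 0.00214. The correlations estimated in the main fit were 0.27 and 0.38, so these p can be too small and do not show a stronger shift. Under this block the limma adjusted p was 0.0851 for miR-155 and 0.0921 for both miR-142-5p and miR-143.

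Lists with fewer than 3 tested members are given as values. Of both tested endothelial members, miR-126 rose and miR-126*, its minor arm, differed by 0.32 (SE 0.10, adjusted p = 0.0716), with a mean of 0.52. Of both tested muscle members, miR-133a rose and miR-133b differed by 0.82 (SE 0.33, adjusted p = 0.147), and the mean of the pair was 8.83 in metformin arrays 1 and 2, 7.70 in arrays 3 and 4, and 7.43 in control tumours. miR-1 and miR-206, also of muscle, were not tested and were each detected on 2 metformin and 0 control arrays. Neither tested red cell member passed: miR-451 differed by -0.35 (SE 0.25), at 9.99 and 9.90 in metformin arrays 1 and 2 and 11.02 and 10.96 in arrays 3 and 4 against a control mean of 10.82, and miR-486-5p differed by 0.0033 (SE 0.07). Of the skin members, miR-205 rose by 0.36 (SE 0.09, adjusted p = 0.0305, and 0.177 with the pair block) and miR-203 differed by -0.05 (SE 0.17). Of the liver and neural list, 2 of 7 members were tested, miR-128 (0.08, SE 0.10) and miR-9 (-0.01, SE 0.10), and neither passed. The liver miRNA miR-122 was detected on 0 of the 8 arrays. Many of these probes cannot tell human from mouse miRNA, since mature sequences are often identical in both species.

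**Figure D3:**
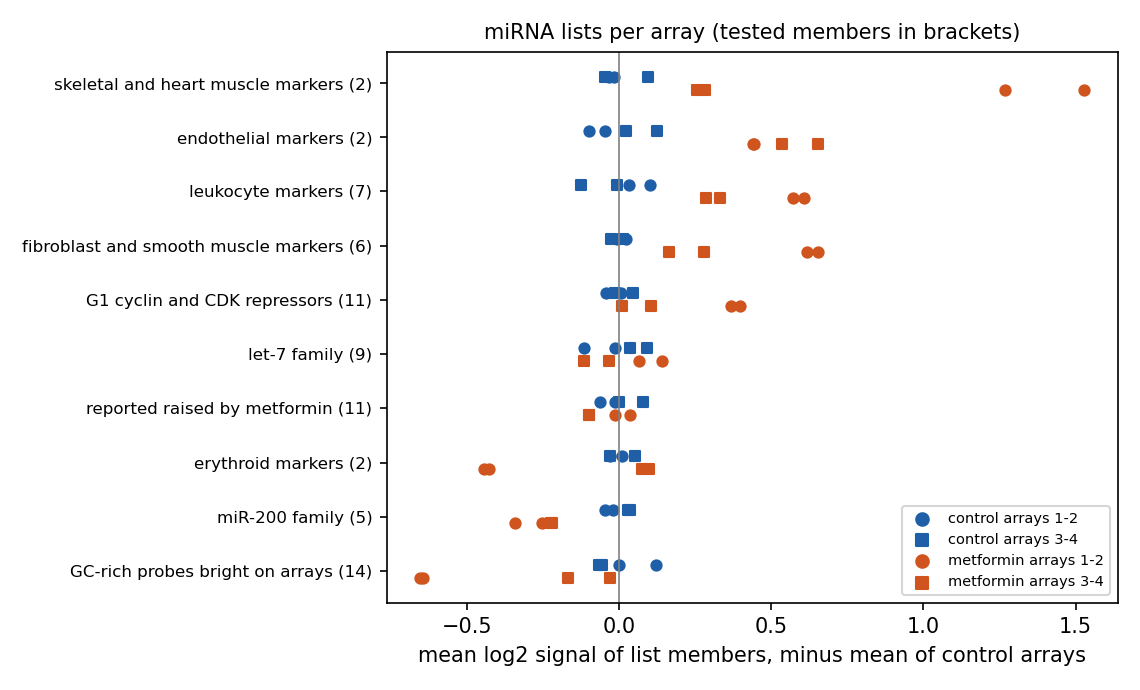
Mean log2 signal of the tested members of 10 miRNA lists on each array, minus the mean of the 4 control arrays (horizontal axis), with the number of tested members in brackets, blue for control and orange for metformin, circles for arrays 1 and 2 and squares for arrays 3 and 4. The leukocyte and the fibroblast lists lie above the controls on all 4 metformin arrays, with differences of the group means of 0.45 and 0.43, and the muscle markers lie farther from the controls in arrays 1 and 2 than in arrays 3 and 4.

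The miR-200 family, epithelial miRNAs that repress ZEB1 and ZEB2, had a lower mean in metformin tumours, by -0.26 in log2 (camera adjusted p = 0.0214, and 0.427 with an estimated correlation). miR-200a fell by 0.44 (SE 0.12, adjusted p = 0.0478), while the other 4 members did not pass, with miR-200b at -0.26 (SE 0.10, adjusted p = 0.134). With the pair block the family's adjusted camera p was 0.0590, and the adjusted p of miR-200a was 0.278. A list of probes had been set down beforehand as rich in GC and bright on arrays whatever the sample, without a check of their sequences. This list also had a lower mean, by -0.37 (camera adjusted p = 0.00135, and 0.487 with an estimated correlation). Of its 14 tested members 4 fell, also 4 when adjusted over the list alone, among them miR-1246, miR-1275 and miR-149* (-0.45, SE 0.10, adjusted p = 0.111 with the pair block). Its mean was 8.71 in metformin arrays 1 and 2 and 9.26 in arrays 3 and 4, against 9.36 in control tumours (exact permutation p = 0.0857).

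The other lists did not pass in camera. Among repressors of the G1 cyclins and their kinases, 3 of 11 members rose (5 over the list alone), miR-195, miR-497 and let-7b (0.32, SE 0.08, adjusted p = 0.0366, and 0.179 with the pair block), with a list mean of 0.22 (camera adjusted p = 0.0561). Of 11 miRNAs reported as raised by metformin in other cancer cells, 1 rose, let-7b, also 1 over the list alone, and the list mean of -0.04 had an adjusted p of 0.508 and turned sign under some scalings. let-7a differed by 0.0046 (SE 0.10), and the mean of the 9 let-7 members by 0.01 (adjusted p = 0.970), with a sign that turned under some scalings. let-7i was at 0.30 (SE 0.10, adjusted p = 0.0928). Of 9 miRNAs reported as raised in cholangiocarcinoma, miR-210 fell and none rose (over the list alone, 1 rose and 1 fell), with miR-25 at 0.35 (SE 0.10, adjusted p = 0.0546) and a list mean of -0.10 (adjusted p = 0.247). miR-21 differed by -0.12 (SE 0.12, adjusted p = 0.555) and held the same normalized value on 7 of the 8 arrays.

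In the miR-29 family miR-29a rose by 0.31 (SE 0.07, adjusted p = 0.0305, and 0.225 with the pair block) and miR-29c fell by 0.64, so the mean of its 3 members, -0.16, had an adjusted p of 0.660. Of the imprinted DLK1-DIO3 cluster, 2 of 12 tested members rose and 1 fell (3 and 1 over the list alone): miR-379 rose by 0.64 (SE 0.11, adjusted p = 0.00880), miR-376a by 0.30 (SE 0.08, adjusted p = 0.245 with the pair block), and the list mean was 0.16 (adjusted p = 0.0893). In the clusters of miR-23, miR-27 and miR-24, miR-27b fell by 0.28 (SE 0.07, adjusted p = 0.0417, and 0.240 with the pair block), miR-23b was at -0.21 (SE 0.07, adjusted p = 0.107), and the list mean of -0.12 (adjusted p = 0.143) turned sign under some scalings. None of the 12 tested members of the miR-17-92 and paralogous clusters passed, miR-17 among them (0.30, SE 0.13), and the list mean was 0.15 (adjusted p = 0.0893). None of the 6 tested p53-induced miRNAs passed, with miR-192 at -0.32 (SE 0.13), miR-34c-5p at -0.24 (SE 0.12) and a list mean of -0.17 (adjusted p = 0.0893). None of the 5 miR-30 members passed, with miR-30c at 0.20 (SE 0.14), miR-30d at -0.17 (SE 0.12), and a list mean of -0.03 (adjusted p = 0.660) whose sign turned under some scalings. Among 4 tested probes now held to be tRNA or rRNA fragments, miR-720 rose by 0.42 (SE 0.10, adjusted p = 0.0305, and 0.177 with the pair block), miR-1260 was at 0.42 (SE 0.16, adjusted p = 0.119), and the list mean was 0.27 (adjusted p = 0.0893).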

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

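In 5 of 166 groups of 4 values, 1 array lay far from the other 3 relative to the whole range, fewer than the 1 in 20 that chance gives. miR-125b was at 12.07 in metformin array 4, against 12.39 to 12.45 in the other metformin arrays. The other 4 were bright probes for which the remaining 3 arrays held a single tied value after quantile normalization. miR-27b was at 12.17 in control array 1 against 12.07. miR-23b was at 14.38 in control array 4 against 14.52, and at 14.38 in metformin array 2 against 14.24. miR-21 was at 14.63 in metformin array 3 against 15.11.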

How the results depend on the processing

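The alternatives with array pairs and with blank spots were chosen after the data were seen. Of the 55 miRNAs that passed, none turned direction under any alternative that tested it. In place of 55, the count was 0 after scaling to the 75th percentile (40 at an unadjusted p under 0.05 in limma), 1 after scaling to the median (miR-1246), 1 with no scaling and 1 with the authors' values (both miR-4688), 152 with array quality weights, 88 by an exact rank-sum test at an unadjusted p under 0.05 and 0 after Benjamini-Hochberg (smallest adjusted p 0.160), 89 at an adjusted p under 0.1, and 2 with a change of at least 2-fold. The rank-sum test gives no p under 0.0286 with 4 arrays per group. Far more than 88 probes at that p would be needed for any to pass Benjamini-Hochberg over 492. That 0 therefore says little about single probes. The residual spread of the 55, which were chosen in the main setting, was larger under the other scalings, as given in the report. The median change of all tested probes was 0.01 in the main setting and 0.12 after scaling to the median, and changes in that setting are to be read against it. Array pairs as a random block gave 11 and as means 0. The count was 24 without control arrays 1 and 2, 35 without control arrays 3 and 4, 6 without metformin arrays 1 and 2 and 115 without metformin arrays 3 and 4. Leaving out 1 array gave 11 to 63.

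The replicate block gave 16 calls. The alternatives not named here gave counts within 1.5 times of 55. Samples with the same number did not deviate together (correlations from -0.22 to -0.14), and none correlated best with its own number. Slide or scan groups as a block were not run, since the files used here name none. Of the 4 lists that passed, none turned direction. Over 28 settings, the miR-200 family lost its call in 7, the fibroblast and the GC-rich list in 3 each, and the leukocyte list in 1. Some lists that had not passed did so in some settings, most often the repressors of the G1 cyclins, in 9. The count of lists was 9 with no filter, 9 with blank spots for detection, where more dim probes and lists were tested, and 0 with an estimated correlation. Leaving out 1 array gave 4 to 6 lists. By exact permutation of list means 0 lists passed in every setting, and 6 had an unadjusted p of 0.0286 in the main setting. With array pairs averaged or left out, too few arrangements remained for this test to pass. The difference in detected probes, -78.75, did not turn or pass. It was 0 with the local background threshold (exact p = 1), -2 with blank spots (exact p = 0.457), and lay between -109.75 and -48.1 with 1 array left out.

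51 values of 14 results turned sign, none of them past a threshold in either setting, and the cause was not tested. Scaling to the 75th percentile gave 0.037 for miR-30d, 0.071 for miR-9, 0.057 for the miR-30 family, 0.035 for the miR-23, miR-27 and miR-24 clusters and 0.017 for the miRNAs reported as raised by metformin. Scaling to the median gave 0.10, 0.14, 0.12, 0.099 and 0.081 for these, and 0.014 for miR-2116*. miR-486-5p was at -0.063 with no scaling and -0.016 with the authors' values, and the let-7 family at -0.0036 and -0.0018. Array weights gave 0.039 for miR-9, -0.039 for let-7a and 0.10 for the miR-30 family. Without control arrays 1 and 2, miR-486-5p was at -0.051, miR-203 at 0.23, miR-128 at -0.056, the let-7 family at -0.050 and the miR-17-92 clusters at -0.023. Without control arrays 3 and 4, miR-9 was at 0.084 and the miR-30 family at 0.11. Without metformin arrays 1 and 2, miR-30c was at -0.039, miR-451 at 0.17, miR-9 at 0.097 and the let-7 family at -0.075. Without metformin arrays 3 and 4, miR-486-5p was at -0.00021, the miR-30 family at 0.13 and the miRNAs reported as raised by metformin at 0.012. With 1 array left out, the range was -0.015 to 0.047 for miR-486-5p, -0.20 to 0.064 for miR-203, -0.073 to 0.079 for let-7a, -0.028 to 0.057 for the let-7 family, -0.077 to 0.034 for miR-9 and -0.099 to 0.029 for the miR-30 family.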

Other observations

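Of the tests in this part, the splits of the arrays and the tests of scaling were chosen before their results were seen, and all others after. miRNAs encoded next to each other had closer changes than random pairs of the tested probes. The genes of 457 of the 492 tested probes were found by name in a human gene table (assembly GRCh38.p14), and 138 pairs of probes with different miRNA numbers had genes within 10 kb. Their log2 changes differed by 0.21 on average, against 0.31 for random pairs (permutation test, 100000 resamples, p = 0.00053), and 94 of the 138 pairs had the same sign, as shared transcription of neighbours may give. The resamples shuffled the changes of all 492 probes, while 112 probes were in pairs, many in several. The test therefore cannot tell an effect of neighbourhood from smaller changes of those 112 probes. Some of these pairs also have similar sequences, which can share signal. The following examples were chosen after their values were seen. miR-143 and miR-145, of 1 cluster, rose by 0.57 and 0.46 (SE 0.11, limma adjusted p = 0.0310). In the DLK1-DIO3 cluster the neighbours miR-379 and miR-494 went opposite ways, at 0.64 and -0.36 (SE 0.10, adjusted p = 0.0451). miR-222 fell by 0.42 (SE 0.10, adjusted p = 0.0303) while miR-221, its neighbour, differed by 0.07 (SE 0.07, adjusted p = 0.596). Under the pair block the adjusted p was 0.113 for miR-145 and for miR-222 and 0.179 for miR-494.

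The real split of the arrays gave 55 calls, and the highest of the other splits gave 0. Only the real split, 1 of the 35, reached the count, the smallest share that 35 splits can give. This argues against a random split as its source only if the 8 arrays are independent, which the close pairs leave open. Only 3 of the 35 keep the array pairs whole, too few for a share under 0.05. With the pairs as units, a random split therefore cannot be excluded. For lists, 14 of the 35 splits gave at least the 4 of the real split, and the highest other gave 6, so chance cannot be excluded for the number of lists. The split of control arrays 1 and 2 with metformin arrays 3 and 4 against the rest, which keeps the pairs whole, was one that gave 6 lists.

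In each group the arrays came in close pairs. Array brightness does not account for the metformin pairs, since 4 of 4 arrays had their nearest array in spike control brightness outside their pair. It stays open for the control pairs, where that held for 1 of 4 arrays and the detected probes (652 and 633 against 488 and 467) parted by pair. Repeat arrays of 1 tumour remain a candidate explanation: the spread between arrays of a pair was 0.07 to 0.12 in log2 over 135 bright probes, against 0.21 to 0.32 between pairs of a group. Spots of a spike control on 1 array had spreads of 0.02 to 0.37, so repeat arrays and different tumours that resemble each other cannot be told apart, and no biological explanation was tested.

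Of the host-cell lists, leukocyte and fibroblast markers passed camera in metformin tumours, a call lost with an estimated correlation, and muscle and endothelial markers had higher means of 2 probes each. The red cell markers, 2 probes, differed by -0.73 (SE 0.27, with arrays taken as independent) from the mean rise of the other 4 host lists. Their mean was 8.73 in metformin arrays 1 and 2 but 9.26 in arrays 3 and 4, against 9.17 in control tumours. More host tissue of every kind is thus argued against in arrays 1 and 2 alone, and by 1 probe, miR-451. The other probe, miR-486-5p, was at 7.52 in both groups, near the detection threshold. Arrays 3 and 4 leave more host tissue of every kind open. The median of 19 host probes exceeded that of all tested probes by 0.42 (SE 0.19, with arrays taken as independent) or more under 3 kinds of scaling. Scaling by 1 factor per array cancels in this difference. The test therefore shows only that the excess is also present without quantile normalization. Without metformin arrays 1 and 2, camera called 1 list higher, the leukocyte list, and the fibroblast list lost its call. The fibroblast mean was 10.29 in metformin arrays 1 and 2 and 9.88 in arrays 3 and 4, against 9.66 in control tumours. A single array pair does not account for the higher mean of the 19 host probes, since metformin arrays 3 and 4 both lay above all controls. Their mean was 0.28 above the control mean. More solid host tissue stays open: the fibroblast list lay -0.17 (SE 0.04) from the mean of the other 3 solid tissue lists, but 15 of the 19 probes were detected on all 4 control arrays, so an even rise need not give equal log2 changes, and changes of single host cell types or of the cancer cells may also account for it. An effect of metformin stays a hypothesis, from as few as 2 tumours per group if each array pair is a single tumour.

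The lower mean of the probes listed as GC-rich rested mainly on metformin arrays 1 and 2. Without these arrays, the mean was -0.10 from the controls, and 1 of the 2 remaining arrays lay below all of them. A difference of that single pair may therefore account for the lower mean of these probes. It does not cover the 4 members that passed, which lay below all control arrays on metformin arrays 3 and 4 too. Of these, miR-1246 was at 10.68 and 10.77 there, against 11.13 or more in control arrays. The raw intensity of the 14 GC-rich probes changed by -469 units (SE 290), and that of the 96 negative control and S-probe spots by -8.13 (SE 5.12). Background as measured on these spots thus covers little of a fall of that size. The difference of -460.8 (SE 287) is under 2 SE, however. A fall of the GC-rich probes beyond background is therefore not established in raw units, and background is not excluded. Scaling stays open too, since their median lay below that of all tested probes by as little as -0.17 (SE 0.19) among 3 kinds of scaling. An effect of metformin on these RNAs stays among the open explanations.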
